A study of Mus musculus with 2 samples.

How the data were processed

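Single-cell RNA was counted in 2 pools of C57BL/6J mice aged 5 weeks, called Dataset A (8 mice, littermates) and Dataset B (7 mice, with no female at 2 h), 8 males and 7 females in all. Per the labels, each mouse received phosphate-buffered saline (PBS, 100 µL) or interferon alpha (IFNα, an antiviral cytokine) into a vein. PBS mice were killed after 1 h and IFNα mice after 1, 2 or 3 h. Mice of Dataset B received 10000 U in 10 µL, and mice of Dataset A received between 5.26 and 7.12 µL of IFNα, for which the labels state no units. Per the labels' protocols, macrophages from the peritoneal cavity and B cells and CD4 T cells from the spleen were sorted, and each mouse was marked with its own hashtag, an oligonucleotide carried by antibodies against MHC class I and CD45. The protocols name the 10x 3' kit for the first 8 mice and its v3 version for the other 7, which are the numbers of mice in Dataset A and Dataset B.

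The deposited expression matrices hold raw UMI counts (unique molecular identifiers) per gene and cell barcode. The authors made them with Cell Ranger, version 6.0.0 for Dataset A and 5.0.0 for Dataset B per the file headers, while the submitters' processing notes name Cell Ranger 6.0, Seurat 3 and the mm10 genome. The deposited hashtag matrices hold raw counts per hashtag and barcode, and the labels do not say which program counted them. Dataset A held 24061 barcodes with 90487472 UMIs (median 2681 per barcode), and Dataset B held 13995 barcodes with 118273253 UMIs (median 5416). Of the 55487 gene IDs, 97.9% were present with the same version in the GENCODE vM21 annotation, from which gene positions (GRCm38) were taken. A symbol named more than 1 gene ID in 114 cases, and gene IDs were used throughout.

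A barcode was given to a mouse with HTODemux in Seurat 5.3.0 (positive quantile 0.99) on centred log-ratio hashtag counts, using the tag that the labels list for each mouse. This left 13898 singlets in Dataset A and 9449 in Dataset B. Cells were kept with at least 500 UMIs, at least 300 genes and a mitochondrial share under 10% (13392 and 9224 cells). Cells were clustered per dataset in scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1), leaving the interferon gene lists and the sex-chromosome genes out of the variable genes. A cluster took the class of which it showed the most marker genes and was left out below 3 detected markers, with markers of 2 classes, or where its top genes pointed to another cell type. The classes are called macrophage-like, B-cell-like and CD4-T-cell-like because they rest on marker genes, and they held 9850 cells in Dataset A and 6359 in Dataset B. Between 20.4% and 34.6% of a mouse's cells were left out at this step.

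The mouse was the replicate. UMIs were summed per mouse and class where at least 20 cells were present, which left out the macrophage-like sum of the Dataset B male at 3 h (1 cell). Class sums ranged from 238951 to 6672207 UMIs in macrophage-like cells, from 516768 to 2558005 in B-cell-like cells and from 684702 to 2472393 in CD4-T-cell-like cells. No pair of sums was identical. Genes were tested in edgeR 4.0.16 by quasi-likelihood (TMM normalization, filterByExpr with a minimum count of 10, robust fit), with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. All adjusted p values of single genes come from edgeR, and errors of log2 changes are standard errors of that fit. The pooled model held dataset (the replicate block), time and sex as additive terms, with 8 residual degrees of freedom in macrophage-like cells and 9 in the other classes. Sex differences were counted without the fixed sex-chromosome list, the sex by IFNα term compared females and males in their change from PBS over the times (within a dataset, only over times that hold both sexes), and differences between classes were fitted with the mouse as a block. Samples, models, tests, gene lists and the rule for named genes were set before the data were examined.

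A further model was chosen after seeing the data, because the datasets moved in opposite directions. It gave every dataset and time its own mean plus a term for sex (5 residual degrees of freedom in macrophage-like cells, 6 in the other classes), and changes were read within Dataset B, within Dataset A as labelled, and as Dataset B minus Dataset A. With 1 mouse at 2 h in Dataset B, and 1 macrophage-like sum at 3 h, a lone mouse is assumed to vary like the other groups. Mice of Dataset A are named by the group that the labels give them.

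The 20 gene lists were tested with camera in limma 3.58.1 (preset correlation 0.01), with camera at an estimated correlation, and with fry. Their p values were adjusted over all lists and contrasts of a class. Counts of list members that passed are given over all genes tested and adjusted over the list alone. The named genes were a panel of 12 interferon-stimulated genes (ISGs) set before the values were seen, of which 1 is left out for a reason apart from its values and 11 are given here: Isg15, Ifit1, Ifit3, Rsad2, Usp18, Irf7, Mx1, Oasl1, Cxcl10, Socs1 and Ly6a. To these came, per class and time, the 4 genes of largest rise and the 4 of largest fall that passed the threshold with the same sign in each dataset alone, which for the values within Dataset B became the 4 and 4 that passed there. Per list, up to 4 members of lowest p past the threshold and the 2 of highest expression not past it were named. For sex, for sex by IFNα and for class differences, the 8 genes of lowest p in each direction were named. Gene models named only by a number and receptor segment genes were counted and passed over.

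The ISG share of a mouse was the percentage of its cells with at least 1000 UMIs whose core ISG count, in 1000 UMIs drawn per cell, exceeded the 95th percentile of PBS cells of the same class and dataset. It was compared between times and PBS with an exact two-sided permutation test of mice, whose smallest possible p is 0.0286 for 4 against 4 mice and 0.0571 for 4 against 3. Intervals and floors cover counting error only. The labels' hashtag assignment was checked with Xist and 4 Y-linked genes. The fits were tested on simulated data with 200 changed genes.

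Alternatives were other size factors in edgeR, DESeq2 1.42.0, no count filter, a minimum count of 50, a minimum absolute log2 change of 1, each dataset alone, no dataset term, the mice of the compared groups alone, sums thinned to the smallest total, a stricter cell filter (1000 UMIs, 500 genes, 5% mitochondrial), hashtags called by a fixed margin (4 times the next tag and at least 10 counts), removal of Scrublet doublets, and each mouse left out. Alternatives chosen after seeing the data were the model above, the times of Dataset A in reverse order, and the ISG share in each dataset alone. Other tools were R 4.3.3, Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9. Droplets without a single hashtag call and the clusters outside the 3 classes were not used in the comparisons.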

Results

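Peritoneal macrophages, splenic B cells and splenic CD4 T cells of 15 mice were profiled to follow how immune cells of both sexes changed over the first 3 h after IFNα. Dataset A held 1 male and 1 female in each of the PBS, 1 h, 2 h and 3 h groups. Dataset B held the same groups without the 2 h female. In all the 2 h group had 3 mice and each of the others 4. The UMIs of a mouse summed over the 3 classes ranged from 1665677 to 10622418. The Dataset A male labelled PBS gave 34 macrophage-like cells and the Dataset B male at 3 h gave 1, while the other mice gave between 107 and 904. Mice gave between 225 and 692 B-cell-like cells and between 150 and 857 CD4-T-cell-like cells.

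The tags matched the labelled sex in all 15 mice. Xist, the RNA that silences 1 X chromosome in females, reached between 400.0 and 538 CPM (UMIs scaled to a common total) in females and between 8.88 and 47.4 in males. The sum of Ddx3y, Eif2s3y, Kdm5d and Uty, which lie on the Y chromosome, reached between 4.22 and 7.18 CPM in females and between 106 and 174 in males. Xist in males lay between 40.2 and 47.4 in Dataset A and between 8.88 and 18.9 in Dataset B.

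Interferon-stimulated genes rose with time after IFNα in Dataset B and fell over the labelled times in Dataset A. The core ISG list sums the transcripts that type I interferon is best known to induce, such as Isg15 (ENSMUSG00000035692, GRCm38 chr4:156199424-156200818), the Ifit genes, Mx1 and Rsad2. In macrophage-like cells of Dataset B it took 6185 CPM in the PBS male and 6668 in the PBS female, 6949 and 11187 at 1 h, 14679 in the male at 2 h, and 28668 in the female at 3 h. In Dataset A the list took 28659 and 32392 CPM in the male and female labelled PBS, 17296 and 25812 in those labelled 1 h, 9114 and 11207 in those labelled 2 h, and 4910 and 5779 in those labelled 3 h. In B-cell-like cells of Dataset B the list rose from 4383 in the PBS male and 4765 in the PBS female to 13713 and 22728 at 1 h, and then took 22796 and 25162 at 3 h. In B-cell-like cells of Dataset A the list took 22805 and 21352 CPM in the mice labelled PBS, 24262 and 24501 in those labelled 1 h, and 5396 and 5666 in those labelled 3 h. In CD4-T-cell-like cells it took 5723 and 6416 in the PBS mice of Dataset B and 19449 and 22940 at 3 h, against 24018 and 26222 in the mice of Dataset A labelled PBS and 6363 and 6329 in those labelled 3 h.

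**Figure D1:**
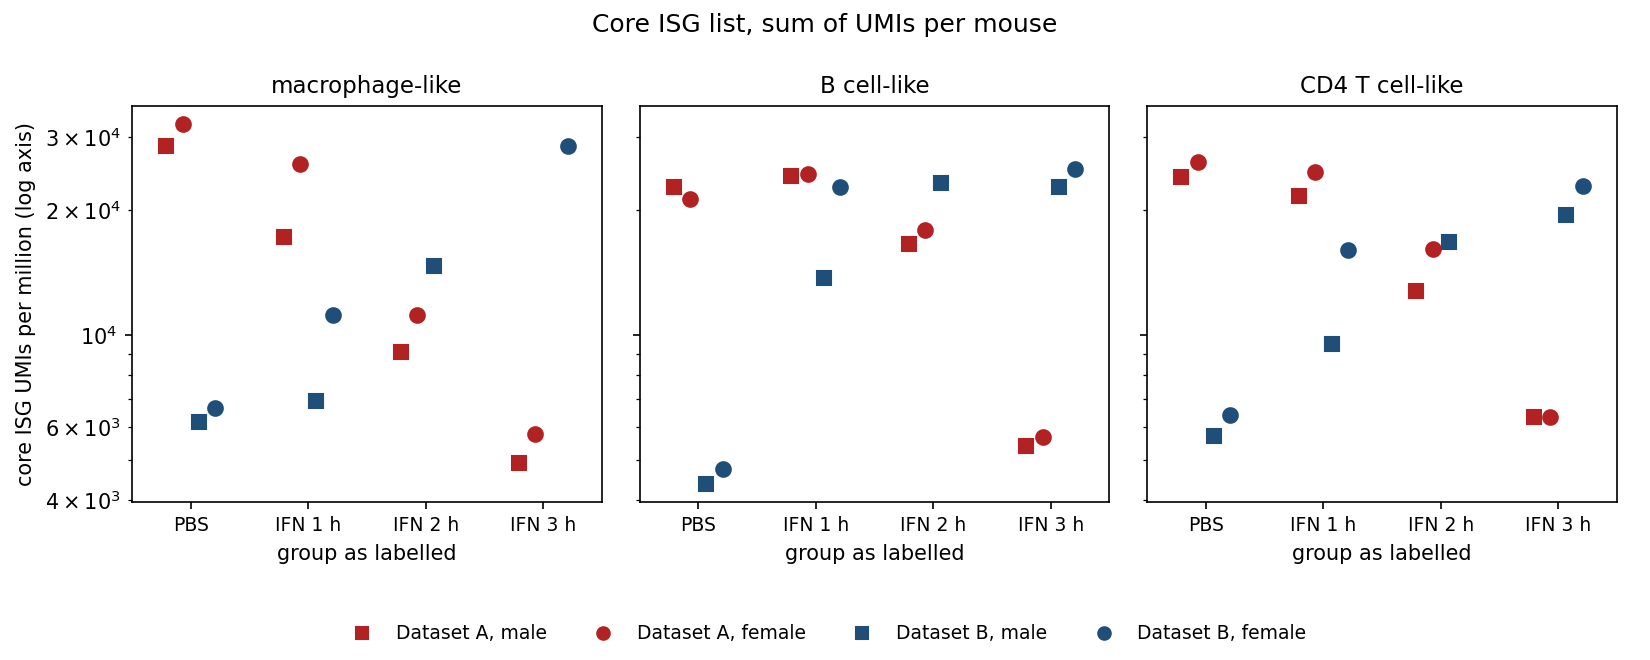
Core ISG CPM in each class, with 1 panel per class, 1 point per mouse, the labelled group on the horizontal axis and a log vertical axis (Dataset A red, Dataset B blue, males squares, females circles). In macrophage-like cells the points of Dataset B lie between 6185 and 28668 and rise with time, and those of Dataset A lie between 4910 and 32392 and fall.

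The test of the difference between the datasets separated them at every time. In macrophage-like cells the change from PBS differed between datasets for 300 genes at 1 h, 1384 at 2 h and 2908 at 3 h of 11769 tested. It differed for 249, 829 and 1901 genes in B-cell-like cells of 9304 tested, and for 124, 357 and 711 in CD4-T-cell-like cells of 9556. Isg15 at 3 h changed by a log2 of 4.64 ± 0.29 in macrophage-like cells of Dataset B and by -4.44 ± 0.27 in those of Dataset A as labelled. The additive fit of both datasets, set before the data were examined, averages these opposite changes and called few genes. In macrophage-like cells edgeR called 0 genes at 1, 2 and 3 h against PBS and at 3 h against 1 h, with 158, 250, 115 and 196 genes at an unadjusted p under 0.05, while DESeq2 called 1, 0, 0 and 2. In CD4-T-cell-like cells edgeR called 1 gene at 1 h, the splicing-related gene Rsrp1 (log2 change 0.43 ± 0.08, adjusted p = 0.0292). It called 0 there at 2 h, at 3 h and at 3 h against 1 h, with 330, 376 and 528 genes at an unadjusted p under 0.05 and 0 called by DESeq2. In B-cell-like cells the additive fit called 15 genes at 1 h, 11 higher and 4 lower. Mir155hg (1.38 ± 0.28), the host transcript of microRNA 155, and Rnf19b (1.14 ± 0.19) were higher. The transcriptional repressors Hes1 (-1.18 ± 0.17) and Id3 (-1.04 ± 0.20) were lower. It called 0 genes at 2 h and 0 at 3 h in that class (631 and 182 at an unadjusted p under 0.05, 1 and 0 by DESeq2), and 40 at 3 h against 1 h. Of these 40 genes 11 were higher and 29 lower at 3 h, with Id3 (1.00 ± 0.19) and Hes1 (1.01 ± 0.18) higher and Mir155hg (-2.0 ± 0.30) lower. The 15 genes became 0 with no dataset term, 0 with thinned sums and 2 with other size factors, and 0 to 57 with each mouse left out (0 without the Dataset A female labelled 1 h). The 40 became 0 with no dataset term or a minimum count of 50. Because the datasets disagreed in direction, the accounts that follow give the changes within Dataset B, with those of Dataset A as labelled beside them.

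In macrophage-like cells of Dataset B the response at 1 h was led by ISGs (2 mice against 2 PBS mice). Mx2, an ISG that the annotation lists as a polymorphic pseudogene, rose by a log2 of 3.18 ± 0.21 (adjusted p = 4.12e-15) and the immunity-related GTPase Iigp1 by 2.90 ± 0.30. Usp18, the protease that damps interferon receptor signalling, rose by 1.80 ± 0.22 and Isg15 by 1.58 ± 0.24 (adjusted p = 0.00208). Stat2 (1.91 ± 0.17), Irf1 (1.17 ± 0.18) and Socs1 (1.72 ± 0.31), which carry or restrain the interferon signal, rose with them. Ifit1 (2.76 ± 0.56, adjusted p = 0.188) and Rsad2 (1.13 ± 0.36, adjusted p = 0.520) did not pass the threshold. The chemokine gene Cxcl10 stood at 1.22 ± 1.14 (adjusted p = 1.00). In all, 148 genes rose and 6 fell, among the latter Rgs2 (-0.74 ± 0.16), a regulator of G-protein signalling, and Ptger4 (-0.71 ± 0.17), a prostaglandin receptor.

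By list, 29 of 54 core ISGs rose in macrophage-like cells at 1 h (42 adjusted over the list alone). So did 8 of 16 GBP and IRG GTPases (11 over the list alone), 13 of 22 nucleic acid sensors (16) and 7 of 21 genes of IFN signalling (8 up and 1 down). Sensors that rose included the DNA-binding PYHIN genes Ifi207 (1.79 ± 0.15) and Ifi204 (1.52 ± 0.16). Of the 21 MHC class I presentation genes, only the peptide transporter Tap1 (0.70 ± 0.18) passed (3 over the list alone), and camera's call for this list (adjusted p = 0.000216) was lost at adjusted p = 0.429 with an estimated correlation. In Dataset A as labelled, 70 genes were higher and 211 lower at 1 h, with Isg15 at -0.91 ± 0.23 (adjusted p = 0.0608) and Irf7 at -1.06 ± 0.17 (adjusted p = 0.000103).

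At 2 h the macrophage-like sum of Dataset B came from 1 male and showed 375 genes higher and 19 lower than PBS. The panel genes that had passed at 1 h all stood higher, with Isg15 at 3.53 ± 0.29 and Usp18 at 3.79 ± 0.25. Ifit1 (5.45 ± 0.63), Ifit3 (3.91 ± 0.54), Rsad2 (3.92 ± 0.41) and Oasl1 (4.30 ± 0.46) now passed. Core ISGs rose in 48 of 54 cases (53 adjusted over the list alone), GBP and IRG GTPases in 14 of 16 (15), nucleic acid sensors in 18 of 22 (18) and IFN signalling genes in 7 of 21 (7 up and 1 down). The first cytokines passed, which were the death ligand gene Tnfsf10 (3.51 ± 0.34), Il15 (2.59 ± 0.32), a growth factor of lymphocytes, and Il18 (0.86 ± 0.24). Falling genes included Plbd1 (-6.73 ± 1.90) and Hpgd (-2.94 ± 0.81), both among the top genes of the monocyte cluster left out in Dataset A. In Dataset A as labelled, 612 genes were higher and 952 lower at 2 h, with Isg15 at -2.37 ± 0.25.

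At 3 h the macrophage-like sum of Dataset B, from 1 female, showed the widest change of its 3 times, with 946 genes higher and 462 lower. The largest rises were in Ccl12 (7.25 ± 1.22, adjusted p = 0.0147), a chemokine that draws monocytes, and Lipg (7.02 ± 0.57, adjusted p = 4.36e-11), the gene of endothelial lipase (ENSMUSG00000053846, GRCm38 chr18:74939322-74961263). Ifit3 rose by 5.90 ± 0.55, Rsad2 by 5.21 ± 0.42, Isg15 by 4.64 ± 0.29 and Irf7, the amplifier of type I interferon production, by 3.57 ± 0.20. Core ISGs rose in 53 of 54 cases (53 adjusted over the list alone), the exception being Ifi27 (-0.11 ± 0.19). GBP and IRG GTPases rose in 15 of 16 cases (15), nucleic acid sensors in 18 of 22 (18), and IFN signalling genes in 9 of 21, with 1 lower (12 up and 1 down). The largest falls were in the kinase gene Nuak1 (-3.68 ± 0.67), the transcription factor Foxq1 (-3.53 ± 0.73) and the cell cycle inhibitor Cdkn2b (-3.47 ± 0.50).

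Of 24 chemokine and cytokine genes in macrophage-like cells 0 passed at 1 h, 3 at 2 h and 11 at 3 h (0, 5 and 13 adjusted over the list alone). The list stood at adjusted p = 0.134 with an estimated correlation at 1 h and held at 2 h and at 3 h (adjusted p = 0.0227 at both). Besides Ccl12 and Cxcl10 (5.24, adjusted p = 0.0294), Tnfsf10 (4.35 ± 0.26), Il18 (2.66 ± 0.20) and Il27 (3.57 ± 0.44) rose. MHC class I presentation passed in 3 of 21 genes at 2 h (4 over the list alone; adjusted p = 0.351 with an estimated correlation). It passed in 15 at 3 h (15 over the list alone; adjusted p = 0.109 with an estimated correlation). Among these were Tap1 (2.52 ± 0.20), the immunoproteasome subunit Psmb9 (1.5 ± 0.19) and Nlrc5 (2.39 ± 0.23), the activator of these genes. The abundant members H2-D1 (0.18 ± 0.17) and B2m (0.31 ± 0.17) did not pass. None of 10 MHC class II genes passed at any time, with Cd74 at -0.14 ± 0.20 at 3 h.

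Other lists moved in part in macrophage-like cells at 3 h. The high-affinity IgG receptor Fcgr1 (3.51 ± 0.21), Fcgr4 (2.09 ± 0.19) and the sialic acid receptor Siglec1 (2.40 ± 0.25) rose. Of 19 phagocytosis genes 5 rose and 1 fell (5 and 1 over the list alone; adjusted p = 0.0457 with an estimated correlation). Of 21 cell death genes 11 rose and 1 fell (13 and 3 over the list alone; adjusted p = 0.0171 with an estimated correlation), among them Mlkl (2.73 ± 0.24), the executor of necroptosis, and Daxx (2.97 ± 0.20). Of 25 trafficking genes 11 rose, such as the checkpoint ligand Cd274 (3.28 ± 0.31), and 2 fell, among them the sphingosine receptor S1pr1 (-2.07 ± 0.25). This list stood at adjusted p = 0.0504 with an estimated correlation (12 and 2 over the list alone). Of 25 resident macrophage genes 4 rose, among them Folr2 (1.36 ± 0.31) and Aspa (1.00 ± 0.21), and Naip1 fell (-1.32 ± 0.25), with Prg4 at 0.06 ± 0.17 (4 and 2 over the list alone). A left-out cluster with Lyve1, Folr2 and Retnla among its top genes held 9.14% of the PBS female's cells, 5.09% of the PBS male's and 0.781% of the 3 h female's, so that such cells were removed unevenly. In the complement list Cfb rose (1.10 ± 0.21) and C5ar1 fell (-0.69 ± 0.19), of 15 genes (2 and 1 over the list alone). Of 24 cholesterol genes the exporter Abcg1 rose (1.36 ± 0.25) and Sc5d (-1.21 ± 0.30) and Scd2 (-2.71 ± 0.90) fell (2 and 2 over the list alone). Of 16 NF-kB feedback genes 3 rose, among them Bcl3 (2.44 ± 0.35) and Cd40 (1.13 ± 0.21), with 4 up and 1 down over the list alone. Of 25 immediate early genes 3 rose, among them Ier3 (0.89 ± 0.19) and Hspa1a (1.55 ± 0.33), with 7 up over the list alone. In this sum 89.9% of cells came from cluster 3 (top genes Ifi205 and Phf11d), while 86.5% of the PBS female's and 97.1% of the PBS male's came from cluster 4 (Slpi and Garnl3). Whether these clusters are states of the same cells was not tested. The B cell markers Ebf1 (1.20 ± 0.34) and Cd79a (0.50 ± 0.20, adjusted p = 0.0921) stood above PBS in the same sum. At 1 h and 2 h these lists had given 2 and 4 risers for cell death (4 and 7 over the list alone; adjusted p = 0.112 and 0.0507 with an estimated correlation). Phagocytosis genes had given 1 and 4 (3 and 4, and 1 down at 2 h; adjusted p = 0.109 and 0.218 with an estimated correlation). Trafficking genes had given 2 and 3 (2 and 6), and immediate early genes 1 and 1 (1 and 1). There were 0 and 1 for NF-kB feedback (0 and 2; adjusted p = 0.527 with an estimated correlation at 1 h), 0 and 1 for cholesterol (0 and 1), and 0 for the resident macrophage and complement lists (0 over the list alone).

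In macrophage-like cells of Dataset B 689 genes were higher at 3 h than at 1 h and 320 lower. Lipg (5.33 ± 0.51), Ifit3 (4.12 ± 0.50), Rsad2 (4.08 ± 0.40), Isg15 (3.06 ± 0.27) and Irf7 (2.65 ± 0.19) were higher at 3 h than at 1 h, and Nuak1 was lower (-3.22 ± 0.72). In Dataset A as labelled 421 genes were higher and 976 lower at 3 h than at 1 h, with Isg15 at -3.53 ± 0.26. Against PBS, 918 genes were higher and 1328 lower in the mice labelled 3 h, and Isg15 stood at -4.44 ± 0.27. Cluster 6 of Dataset A (with Slfn4 and Rsad2 among its top genes) held 94.5% and 82.4% of the macrophage-like cells of the female and male labelled PBS and 0.434% and 1.53% of those labelled 3 h.

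In B-cell-like cells of Dataset B 571 genes were higher and 159 lower at 1 h, in 2 mice against 2 PBS mice. Ifit3 rose by a log2 of 4.74 ± 0.34, Usp18 by 3.67 ± 0.23, Oasl1 by 3.26 ± 0.18 (adjusted p = 4.42e-22) and Isg15 by 3.20 ± 0.34. The largest rise was in Rilpl1 (5.27 ± 0.53; ENSMUSG00000029392, GRCm38 chr5:124493080-124531391), a regulator of vesicle traffic that rose by 6.16 ± 0.58 at 2 h and 5.39 ± 0.56 at 3 h. The costimulator Cd86 (1.72 ± 0.19), the retention receptor Cd69 (1.91 ± 0.18) and Myc (1.54 ± 0.17) rose, and the phosphatase Dusp10 (-1.66 ± 0.41), Dusp2 (-0.85 ± 0.13), Jund (-0.56 ± 0.09) and Egr3 (-1.19 ± 0.21) fell. The B-cell-like sums compared came from different clusters. Cluster 11 (top genes Fcer2a and Tnfrsf13c, with Cd55, Ciita, H2-DMb2 and Ebf1 among the next) held 71.8% of the PBS female's and 80.9% of the PBS male's cells. It held 8.66% and 28.5% at 1 h, 6.53% in the male at 2 h, and 2.24% and 8.8% at 3 h. At 3 h 39.9% and 52.0% came from cluster 12 (Ighd and Fcmr) and 33.6% and 19.6% from cluster 6 (Hmgn3 and Vpreb3). Whether these clusters are states of the same cells was not tested.

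Nearly the whole core ISG list rose in B-cell-like cells at each time, with 51, 52 and 52 of 53 members at 1, 2 and 3 h (51, 52 and 52 up and 0, 0 and 1 down adjusted over the list alone). GBP and IRG GTPases rose in 15 of 16 cases at each time (15 over the list alone). Nucleic acid sensors rose in 14, 16 and 14 of 23 (16, 17 and 15), led by Ifi213, at 2.58 ± 0.14, 3.16 ± 0.16 and 3.02 ± 0.14. Of 21 IFN signalling genes 8, 8 and 9 rose and 2, 2 and 0 fell (over the list alone 10, 8 and 10 rose and 3, 3 and 2 fell). The list stood at adjusted p = 0.0606 with an estimated correlation at 2 h and at 3 h. MHC class I presentation rose in 16, 17 and 19 of 21 genes (18, 18 and 20 over the list alone). Nlrc5 stood at 1.76 ± 0.21 at 1 h and 2.50 ± 0.21 at 3 h, and the proteasome activator Psme1 at 1.19 ± 0.09 at 3 h. The list's call was at adjusted p = 0.0606 with an estimated correlation at 1 h and held at 2 h and 3 h. The cell death list rose in 7, 6 and 6 of 18 genes (7 over the list alone at each time, and 1 fell at 3 h), at adjusted p = 0.0606, 0.0606 and 0.0877 with an estimated correlation. Daxx (2.20 ± 0.15), Pml (1.61 ± 0.12) and Casp4 (1.73 ± 0.22) led it at 1 h.

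MHC class II genes, which present antigen to CD4 T cells, fell in B-cell-like cells at 3 h, in 7 of 11 cases (8 adjusted over the list alone). H2-Aa (ENSMUSG00000036594, GRCm38 chr17:34282744-34287823) fell by 0.53 ± 0.07 on the log2 scale, H2-Ab1 by 0.44 ± 0.07 and H2-Eb1 by 0.43 ± 0.08, and 0 of the 11 passed at 1 h and 2 h (0 over the list alone). The camera call at 3 h (adjusted p = 0.000297) stood at adjusted p = 0.326 with an estimated correlation. Of the B cell receptor list 4 of 17 genes fell at 3 h, which were the IgE receptor Fcer2a (-1.12 ± 0.15), the lineage factor Ebf1 (-0.55 ± 0.08), Tnfrsf13b (-0.54 ± 0.13) and Cr2 (-0.63 ± 0.18). In that list 2 genes rose and 4 fell at 1 h, and 1 rose and 5 fell at 2 h (over the list alone 2 and 5, 2 and 7, and 1 and 6). It stood at adjusted p = 0.225, 0.0866 and 0.0737 with an estimated correlation. Cd79a, the signal chain of the receptor, did not pass (-0.10 ± 0.06 at 3 h).

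At 2 h (1 male) 602 genes were higher and 175 lower in B-cell-like cells, and at 3 h (2 mice) 723 were higher and 412 lower. Irf7 climbed from 2.04 ± 0.23 at 1 h to 3.05 ± 0.26 and 3.19 ± 0.23, and Ly6c2, a surface antigen, stood at 2.56 ± 0.24 at 2 h and 3.22 ± 0.19 at 3 h. Il15 (3.84 ± 0.53 at 2 h), Il18 (1.61 ± 0.38 at 3 h) and Tnfsf10 (2.62 ± 0.40 at 1 h) rose. In their chemokine and cytokine list 3, 4 and 3 of 13 genes passed (3, 4 and 4 over the list alone), at adjusted p = 0.240, 0.264 and 0.239 with an estimated correlation. The chaperone genes Hspe1 (0.94 ± 0.10), Hsp90aa1 (0.92 ± 0.12) and Hsph1 (1.09 ± 0.23) rose at 3 h among 6 risers and 1 faller of 23 immediate early and stress genes (7 and 3 over the list alone). In this list 4 rose and 4 fell at 1 h, and 3 rose and 1 fell at 2 h (7 and 4, and 4 and 1). The largest rise at 2 h was in Jchain (8.52 ± 0.91), a marker of antibody-secreting cells, in the single male of that time.

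In B-cell-like cells the trafficking list rose in 10, 8 and 8 of 24 genes and fell in 3, 1 and 1 (10, 10 and 8 up and 3, 3 and 2 down over the list alone). It stood at adjusted p = 0.0801, 0.0801 and 0.0549 with an estimated correlation, with Ly6a at 1.75 ± 0.10 at 3 h. Of 19 cholesterol genes 1, 1 and 4 fell (1, 1 and 4 over the list alone), among them Scd1 (-0.55 ± 0.13 at 1 h) and Sc5d (-1.17 ± 0.39 at 3 h). The complement regulator Cd55 fell at each time (-0.92 ± 0.13 at 3 h), 1 of 13 complement genes (1 over the list alone). Cytosolic ribosomal protein genes rose slightly at 1 h, 20 of 86 (55 over the list alone), with Rps20 at 0.21 ± 0.05, and 0 at 2 h and 3 h. Camera's adjusted p of 0.000239 became adjusted p = 0.682 with an estimated correlation. Rel (0.56 ± 0.12 at 1 h) alone passed of 15 NF-kB feedback genes (1 over the list alone), and Il6ra (-1.07 ± 0.34 at 3 h) alone of 13 T cell genes (1 up and 2 down over the list alone). Of 24 resident macrophage genes Saa3 (0.31 ± 0.10 at 1 h) and Cd9 (-0.69 ± 0.20 at 3 h) passed (0 and 1 over the list alone). In the remaining list 0 of 16 phagocytosis genes passed in edgeR.

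In B-cell-like cells of Dataset B 396 genes differed between 3 h and 1 h, 231 higher at 3 h and 165 lower. Ly6c2 (2.32 ± 0.17), Irf7 (1.15 ± 0.19) and Ly6a (0.67 ± 0.09) were higher at 3 h and Mir155hg lower (-1.79 ± 0.38). Isg15 (0.51 ± 0.29, adjusted p = 0.491) and Ifit3 (-0.41 ± 0.26, adjusted p = 0.553) did not pass. In Dataset A as labelled 266 genes were higher and 715 lower at 3 h than at 1 h, with Isg15 at -3.31 ± 0.35. Against PBS as labelled, 68 genes were higher and 30 lower at 1 h, 150 and 178 at 2 h, and 380 and 659 at 3 h, with Isg15 at 0.26 ± 0.30, -0.49 ± 0.31 and -3.05 ± 0.35. Cluster 1 of Dataset A (top genes Igkc and Ms4a1) held 67.4% and 73.4% of the B-cell-like cells of the female and male labelled PBS and 9.54% and 11% of those labelled 3 h.

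In CD4-T-cell-like cells of Dataset B 187 genes rose and 29 fell at 1 h, at 2 h (1 male) 241 and 13, and at 3 h 270 and 31. Ifit1 rose by a log2 of 3.43 ± 0.38 at 1 h and 3.58 ± 0.39 at 3 h, Isg15 by 2.62 ± 0.32 and 3.60 ± 0.32, and Irf7 by 1.22 ± 0.13 and 2.48 ± 0.13 (adjusted p = 8.77e-36). Bst2, which tethers budding virus to the cell, rose by 2.74 ± 0.10 at 3 h, Ifi44 by 4.23 ± 0.45 and the stem cell antigen Ly6a by 2.17 ± 0.10. Mx1 rose by less than in the other classes (0.86 ± 0.22 at 2 h and 0.69 ± 0.21 at 3 h), and Cxcl10 did not pass at any time (-0.27 ± 0.41 at 3 h).

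Core ISGs rose in 40, 48 and 51 of 53 cases in CD4-T-cell-like cells at 1, 2 and 3 h (50, 51 and 52 adjusted over the list alone), and 1 fell at 3 h. GBP and IRG GTPases rose in 14, 16 and 16 of 16 cases (16 over the list alone at each time), with Irgm1 at 1.62 ± 0.15 at 1 h and Gbp2 at 2.10 ± 0.16 at 3 h. Nucleic acid sensors rose in 9, 11 and 11 of 22 (11, 12 and 13), with Mndal at 1.70 ± 0.09 at 3 h. IFN signalling genes rose in 9 of 21 at each time (10, 9 and 10, and 1 fell at 3 h). MHC class I presentation rose in 4, 11 and 16 of 21 genes (9, 16 and 18), with Psmb8 at 0.94 ± 0.08 and Tapbp at 1.25 ± 0.11 at 3 h. Its call was at adjusted p = 0.0687 with an estimated correlation at 1 h and held at 2 h and 3 h. The survival gene Bcl2 fell at 3 h (-0.89 ± 0.19) among 3 risers and 2 fallers of 25 trafficking genes (7 and 5 over the list alone; adjusted p = 0.0687 with an estimated correlation). There were 3 and 1 at 1 h and 4 and 1 at 2 h (4 and 4, and 5 and 4). Daxx (2.05 ± 0.23) and Casp8 (0.80 ± 0.14) rose at 3 h in the cell death list. Of its 19 genes 3, 4 and 3 rose (4, 5 and 5) and 0, 1 and 1 fell (0, 2 and 1), at adjusted p = 0.0504, 0.0687 and 0.0687 with an estimated correlation.

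The other lists gave 0 to 2 calls in CD4-T-cell-like cells. Il7r (0.48 ± 0.09 at 1 h), the interleukin 7 receptor, alone passed of 17 T cell receptor and fate genes, and the receptor chain Cd3e stood at -0.02 ± 0.09 at 3 h. Tnfsf10 alone passed of 15 chemokine and cytokine genes (1.09 ± 0.31 at 1 h and 1.67 ± 0.32 at 2 h, and over the list alone 1 gene also fell at 1 h). Nfkb1 (0.55 ± 0.16) and Bcl3 (1.01 ± 0.30) passed of 15 NF-kB feedback genes at 3 h (2 over the list alone, and 1 at 2 h), and Junb (0.47 ± 0.14) and Jund (-0.39 ± 0.10) of 21 immediate early genes at 1 h (1 up and 2 down over the list alone, and 1 down at 2 h). In edgeR 0 genes passed at any time in the MHC class II, cholesterol, resident macrophage, complement, phagocytosis and B cell receptor lists of this class. The mitochondrial genome list gave 0 calls in any class and at any time within Dataset B, and ribosomal protein genes 0 in macrophage-like and CD4-T-cell-like cells, each also 0 over the list alone.

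In CD4-T-cell-like cells of Dataset B 102 genes were higher at 3 h than at 1 h and 16 lower, among them Bst2 (1.88 ± 0.09), Ly6a (1.49 ± 0.09) and Irf7 (1.26 ± 0.11) upward and Fkbp5 (-1.14 ± 0.26) downward. In Dataset A as labelled, 0 genes were higher and 5 lower at 1 h, 15 and 161 at 2 h, and 112 and 479 at 3 h, with Isg15 at 0.04 ± 0.26, -0.98 ± 0.27 and -3.38 ± 0.31. At 3 h against 1 h 103 were higher and 446 lower. Cluster 3 of Dataset A (top genes Ly6c1 and Gbp8) held 57.3% and 62.5% of the CD4-T-cell-like cells of the female and male labelled PBS and 2.57% and 2.7% of those labelled 3 h.

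**Figure D2:**
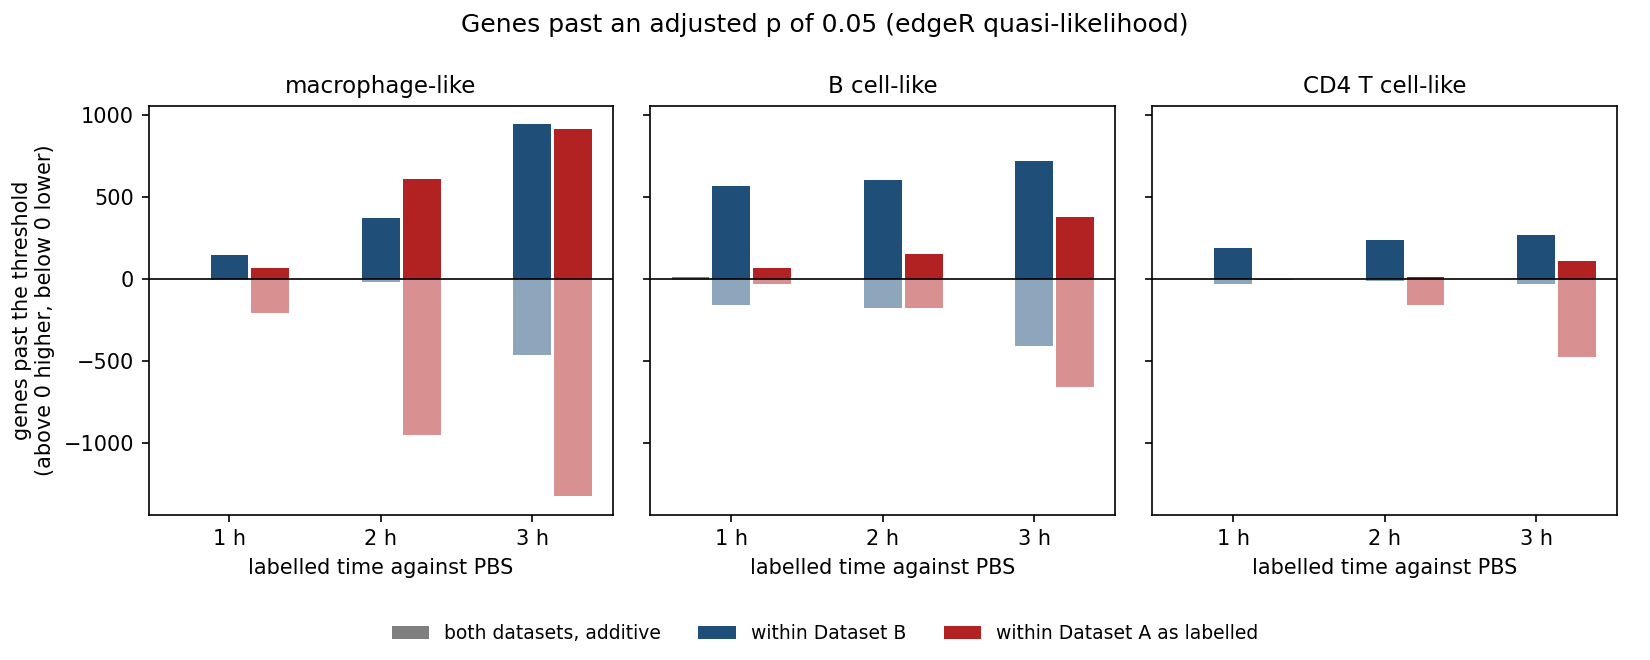
Number of genes past the threshold in each class at each time against PBS, higher above 0 and lower below 0, in the additive fit (grey), within Dataset B (blue) and within Dataset A as labelled (red). Dataset B rises to 946 genes higher at 3 h in macrophage-like cells, where Dataset A as labelled has 1328 genes lower.

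The size of the IFNα response differed between classes. Macrophages came from the peritoneal cavity and lymphocytes from the spleen, so that class and tissue cannot be told apart in contrasts with macrophage-like cells. The macrophage-like sums of Dataset B at 2 h and 3 h came from 1 mouse each. Over the 3 times in Dataset B, the log2 change was higher in macrophage-like than in B-cell-like cells for 158 genes and lower for 192, of 11567 tested. The PYHIN sensors Ifi211 (difference in log2 change 2.28 ± 0.31), Ifi207 (1.98 ± 0.27) and Ifi204 (1.73 ± 0.25), Slfn4 (1.87 ± 0.24) and Rsad2 (1.13 ± 0.16) had the higher change in macrophage-like cells. Bst2 (-1.92 ± 0.14), Rilpl1 (-4.83 ± 0.54), the oxidase subunit Cybb (-1.67 ± 0.13), Ifitm3 (-1.30 ± 0.14) and Cd86 (-1.99 ± 0.22) had it in B-cell-like cells. Against CD4-T-cell-like cells, 106 genes had a higher change in macrophage-like cells, with Mx1 at 2.27 ± 0.24, Ifi204 at 2.35 ± 0.28 and Rsad2 at 1.68 ± 0.18, and 20 a lower one, with Ly6a at -1.16 ± 0.19 and Bst2 at -0.95 ± 0.14. The change in B-cell-like cells was above that in CD4-T-cell-like cells for 138 genes, with Ifit2 at 2.80 ± 0.27, Mx1 at 1.98 ± 0.25 and Ifi47 at 1.56 ± 0.15, and below it for 18, with Gpr183 at -0.77 ± 0.17, a receptor that guides lymphocytes. In the additive fit of both datasets edgeR called 0 genes for each pair of classes (557, 280 and 403 at an unadjusted p under 0.05), and DESeq2 called 30, 0 and 0. In Dataset A as labelled the same contrasts called 737, 489 and 52 genes.

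**Figure D3:**
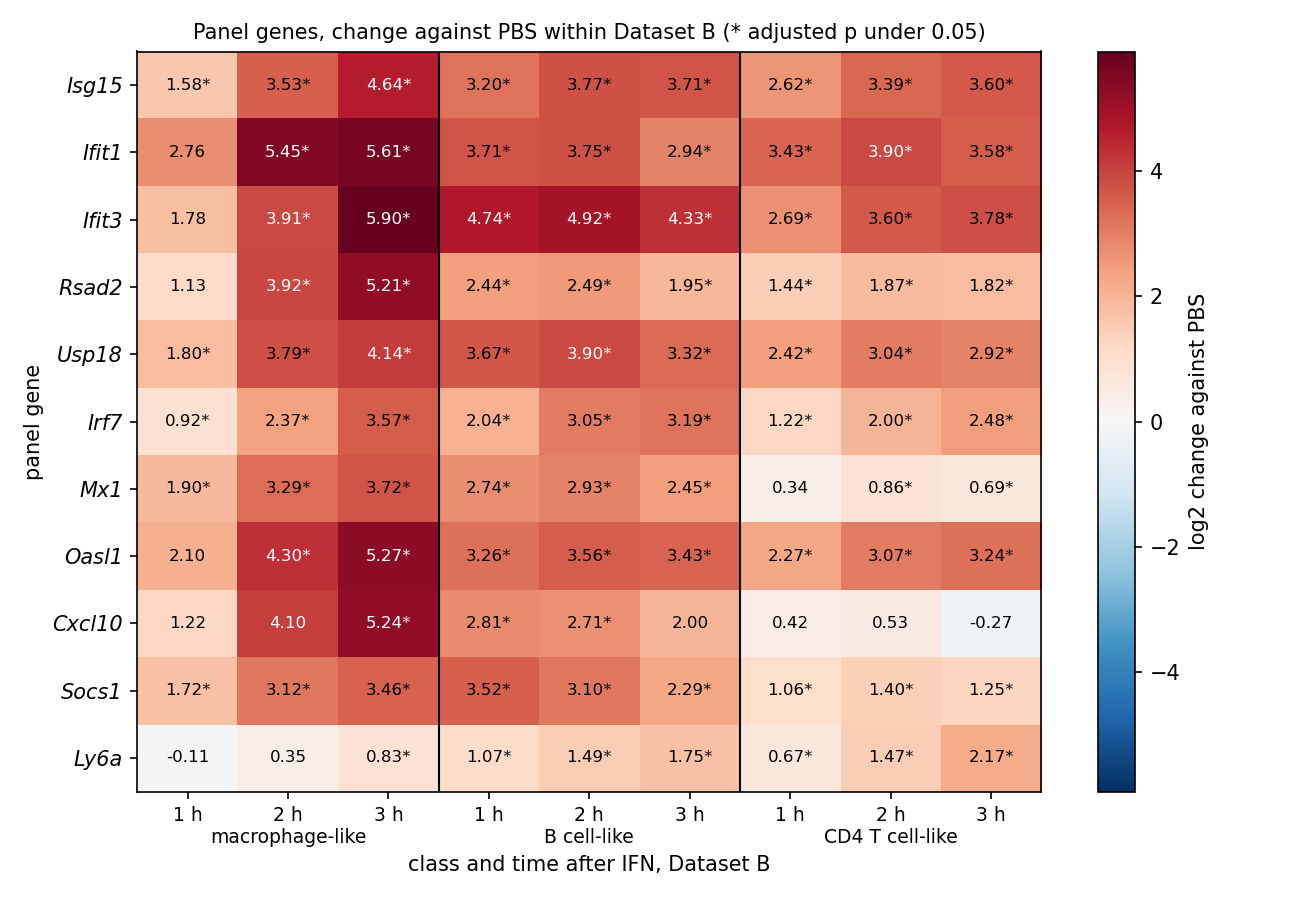
Log2 change against PBS of 11 panel genes within Dataset B in each class at 1, 2 and 3 h, with an asterisk at an adjusted p under 0.05. Ifit3 in macrophage-like cells at 3 h reads 5.90 and Cxcl10 in CD4-T-cell-like cells at 3 h reads -0.27.

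Females were compared with males across all times. In the additive fit of macrophage-like cells 10 genes outside the sex-chromosome list were higher in females and 15 lower (4 females and 4 males in Dataset A, 3 and 3 in Dataset B). The lipid carrier gene Apoe (0.72 ± 0.08, adjusted p = 0.00136), the scavenger receptor Stab1 (0.83 ± 0.13) and complement C4b (0.50 ± 0.09) were higher in females. The protease inhibitor Slpi (-1.22 ± 0.12, adjusted p = 0.000274), the calcium-binding genes S100a4 (-1.01 ± 0.09) and S100a6 (-0.95 ± 0.12) and the cell cycle inhibitor Cdkn2a (-1.36 ± 0.19) were higher in males. With a mean for each dataset and time, 362 genes were higher in females and 220 lower, with Apoe at 0.75 ± 0.08 and Slpi at -1.24 ± 0.09. In that model 36 of 54 core ISGs were higher in macrophage-like cells of females and 1 lower (44 and 1 adjusted over the list alone; adjusted p = 0.119 with an estimated correlation). Ifi205 stood at 1.25 ± 0.12 and Oasl2 at 0.81 ± 0.10. The same model gave 15 of 22 nucleic acid sensors, 11 of 16 GBP and IRG GTPases and 7 of 19 phagocytosis genes higher in females (16, 14 and 8 over the list alone, where 2 phagocytosis genes were lower). Each stood at adjusted p from 0.119 to 0.123 with an estimated correlation.

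In lymphocytes the additive fit called 0 genes outside the sex-chromosome list in B-cell-like and in CD4-T-cell-like cells (262 and 342 at an unadjusted p under 0.05, 0 and 0 by DESeq2), while Xist was higher in females by 4.14 ± 0.46 and 4.49 ± 0.24. With a mean for each dataset and time, 9 genes were higher and 9 lower in B-cell-like cells of females, with Ly6c2 at 0.61 ± 0.13 and Fcer2a at -0.46 ± 0.08. In CD4-T-cell-like cells 50 were higher and 4 lower, among them Gbp2 (0.50 ± 0.08), Irf7 (0.37 ± 0.07) and Oas3 (0.49 ± 0.09). In this class 18 of 53 core ISGs passed (38 over the list alone; adjusted p = 0.103 with an estimated correlation). In B-cell-like cells 0 of 53 core ISGs passed (3 over the list alone; adjusted p = 0.542 with an estimated correlation), and 2 of 11 MHC class II genes were lower in females (6 over the list alone; adjusted p = 0.503). Dataset B alone called 125 genes in B-cell-like and 87 in CD4-T-cell-like cells, against 235 in macrophage-like cells, and Dataset A alone 3, 16 and 525. The sex difference was not tested between classes.

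Whether the response to IFNα differed between sexes was tested as a sex by IFNα term. This term of the additive fit called 0 genes in each class (93, 199 and 328 at an unadjusted p under 0.05 in macrophage-like, B-cell-like and CD4-T-cell-like cells), and DESeq2 also called 0, in a fit that averages the opposite changes of the datasets. Within Dataset B, in a fit of both datasets with 2 residual degrees of freedom in macrophage-like and 3 in the other cells, 7 genes passed in macrophage-like cells, where Ifit3 (1.86 ± 0.34), Ms4a6c (1.39 ± 0.30) and the chemokine Ccl2 (3.06 ± 0.65) had the higher change in females and Retnla (-2.05 ± 0.31) the lower. Retnla is a top gene of the unevenly removed cluster named above, which held 6.40% of the 1 h female's cells and 1.27% of the 1 h male's. In B-cell-like cells 8 passed, among them the hemoglobin genes Hba-a1 (1.80 ± 0.18) and Hbb-bt (1.64 ± 0.19), which are abundant in red cells, and Ifitm3 (0.87 ± 0.17) and Cd69 (1.07 ± 0.24). With a margin required between hashtags Hba-a1 stood at 0.1 and Hbb-bt at -0.21, and neither passed. In CD4-T-cell-like cells edgeR called 0 (475 at an unadjusted p under 0.05, 0 by DESeq2). The term called, in Dataset A as labelled, 6 genes in macrophage-like cells, 1 in B-cell-like cells, lower in females, and 0 in CD4-T-cell-like cells (448 at an unadjusted p under 0.05). In the Dataset B macrophage-like sums the 2 h and 3 h groups hold 1 mouse each, so that the term there rests on 1 mouse of each sex at 1 h and at PBS, and its spread comes from Dataset A.

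The share of single cells above the PBS range was counted in each mouse. A cell was counted when its core ISG UMIs, at an equal depth of 1000 UMIs, exceeded the 95th percentile of the PBS cells of its class and dataset. Such a share does not separate a shift of all cells from a response of some. Among B-cell-like cells of Dataset B the share was 86.4% in the female and 55.2% in the male at 1 h, and 91.5% in the male at 2 h. At 3 h 249 of 262 cells in the female and 231 of 243 in the male lay above it. Among CD4-T-cell-like cells the share was 48.4% in the female and 18.2% in the male at 1 h, 55.0% in the male at 2 h and 89.3% and 71.8% at 3 h. Among macrophage-like cells it was 38.3% in the female and 5.11% in the male at 1 h, 61.7% in the male at 2 h and 99.4% in the female at 3 h. In Dataset A, where the threshold came from the mice labelled PBS, no mouse passed 9.86%. The share was 0 in both mice labelled 3 h in each class (of 590 and 302 B-cell-like, 758 and 403 CD4-T-cell-like, and 459 and 391 macrophage-like cells). With the datasets pooled, the lowest exact permutation p was 0.114, for B-cell-like cells at 1 h (mean difference 34.1 points, 4 mice against 4, and 18.3 without the Dataset B female at 1 h), and every adjusted p of these exact tests was 0.857.

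**Figure D4:**
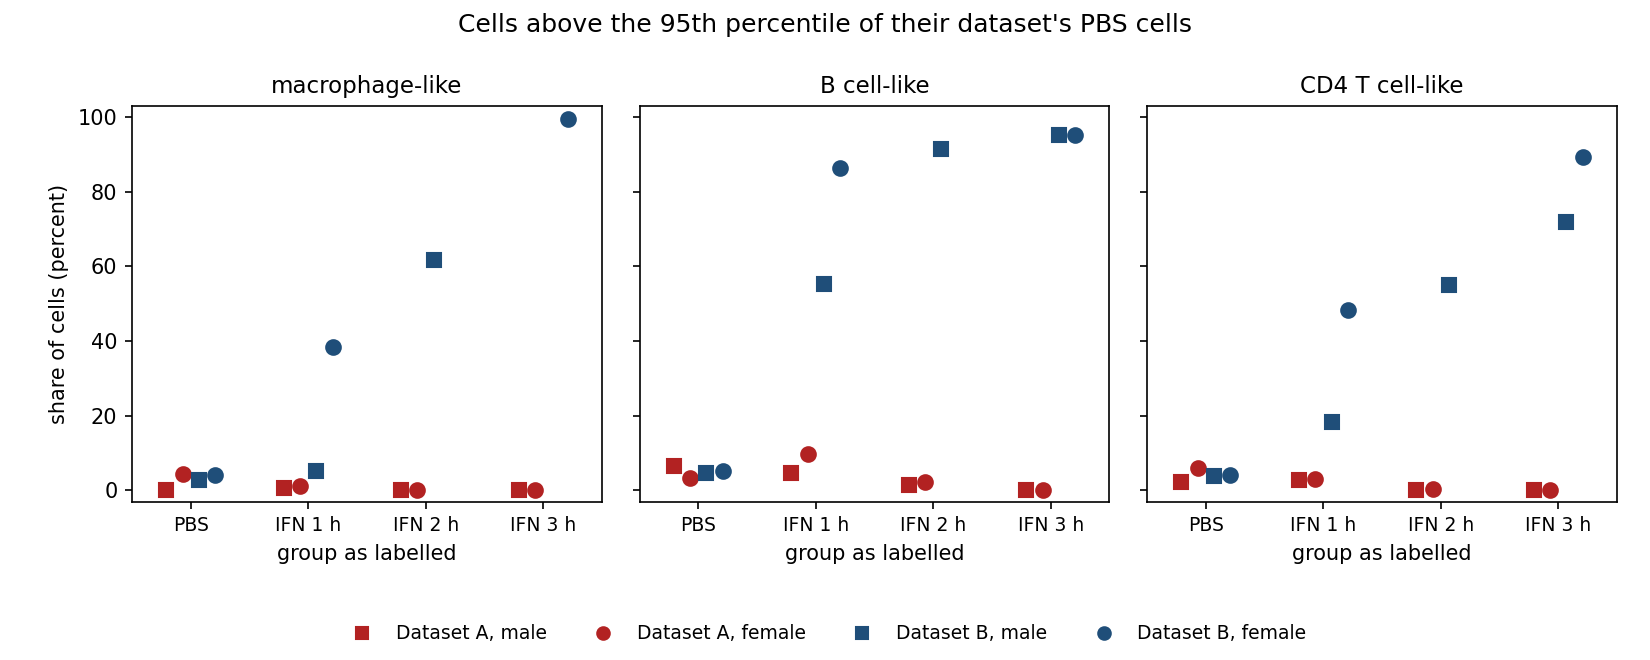
Share of cells above the 95th percentile of the PBS cells of their dataset, with 1 panel per class and 1 point per mouse at its labelled group (Dataset A red, Dataset B blue). Dataset B reaches 99.4% in macrophage-like cells at 3 h and Dataset A stays at or under 9.86%.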

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

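The tests of wrong tag calls, of a lower dose or earlier peak and of the injected volume were chosen only after the result was seen. Interferon genes that rose in Dataset B fell over the labelled times of Dataset A, as the tests of the difference between the datasets show. In macrophage-like cells the change differed between datasets for 300 genes at 1 h, 1384 at 2 h, 2908 at 3 h and 2005 at 3 h against 1 h. In B-cell-like cells these were 249, 829, 1901 and 1009 genes, and in CD4-T-cell-like cells 124, 357, 711 and 472. Of the 1408 genes called within Dataset B at 3 h in macrophage-like cells, 1148 were also called in Dataset A, 1147 with the opposite sign. In B-cell-like cells at 1 h 56 of the 60 genes called in both had the same sign, of 730 called in Dataset B, and the correlation over all genes was 0.161.

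The first pattern weighed was the order of core ISG levels in Dataset A. Cells given to a mouse of the other sex would blur the sexes. The highest Y-linked level of a female was 6.41% of the lowest male in Dataset A, which argues against this. The check cannot see cells exchanged between mice of the same sex, so that wrong calls of that kind remain open. A lower dose or an earlier peak leaves mice without IFNα at a low level, but core ISG levels in the lower mouse labelled PBS were at least 3.77 times those in the higher mouse labelled 3 h in each class, which argues against it. Time labels listed in reverse remain open: among genes outside the fixed lists the reversed order had the highest of 24 correlations with Dataset B in 2 of 3 classes, with 0.767 in macrophage-like and 0.701 in B-cell-like cells (next 0.62 and 0.696), and ranked 2 in CD4-T-cell-like cells (0.744, against 0.763 for an order that also exchanges the pairs labelled PBS and 1 h). The order as labelled ranked 24 (-0.666), 15 (-0.162) and 22 (-0.455) in macrophage-like, B-cell-like and CD4-T-cell-like cells. In each class the order of highest correlation took the pair labelled 3 h as PBS. The classes differed only in the pairs taken as 2 h and 3 h. The labels list 2 tags for PBS in Dataset A that they list for 3 h in Dataset B. The tag list may be where an exchange arose, and the classes leave its full order undecided.

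The second pattern was the higher core ISG level of females in macrophage-like sums, seen in 6 of 6 pairs of 1 dataset and labelled time, at a median ratio of 1.21. A larger injected volume in females is argued against by the labels. Females of Dataset A were given less IFNα volume than males, and all IFNα mice of Dataset B received 10 µL. The lowest ratio of the 3 pairs labelled IFNα in Dataset A was 1.18. It adds no further test, because no female received more than the male of its pair. A different mix of the clusters kept is argued against by the ratio within clusters, at a median of 1.21 and above 1 in 7 of 7 pairs. A biological difference between sexes remains open, as does an uneven removal of other cells. With a mean for each dataset and time, S100a4 (-1.03 ± 0.09), S100a6 (-1.01 ± 0.10), Slpi (-1.24 ± 0.09), Vim (-0.70 ± 0.10) and Lgals3 (-0.63 ± 0.09) were lower in females, and a left-out cluster of Dataset A with Slpi, Arg1 and S100a4 on top held 2.68% to 8.66% of the cells of males and 0.677% to 1.40% of those of females. In the same model 36 of 54 core ISGs were higher in females, and the list stood at adjusted p = 0.119 with an estimated correlation.

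Other splits of the mice were counted for the fit of only the groups compared, with the datasets as a term. Where the real split gave 0 genes every split gives as many, so that its count of splits says nothing about chance. At 1 h the real split gave the most genes in B-cell-like cells (264 genes, 1 of 33 splits, highest other 211). This is the lowest share that 33 splits can give, and it was not adjusted for the number of comparisons, so that chance is not excluded. Nor can chance be excluded in macrophage-like cells (4 genes, 3 of 33, highest other 118) or CD4-T-cell-like cells (10 genes, 3 of 33, highest other 112). At 2 h it cannot be excluded in B-cell-like cells (6 genes, 6 of 33, highest other 277), and the real split gave 0 genes in macrophage-like (33 of 33, highest other 749) and CD4-T-cell-like cells (33 of 33, highest other 294). At 3 h the real split gave 0 genes in each class, and 33 of 33 splits as many, with highest others of 2745, 1992 and 690, each from the split that groups the pair labelled PBS in Dataset A with the 3 h mice of Dataset B. These splits point to a structure of the samples, the opposite order of the datasets; the values within each dataset are given in the report. At 3 h against 1 h chance cannot be excluded in B-cell-like cells (26 genes, 3 of 33, highest other 222), and the real split gave 0 genes in macrophage-like (33 of 33, highest other 1245) and CD4-T-cell-like cells (33 of 33, highest other 133), each highest from the split that groups the pair labelled 1 h in Dataset A with the 3 h mice of Dataset B.

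For sex in the additive fit, 3 of 99 splits gave as many genes as the real split in macrophage-like cells (25 genes), a share under 0.05. The highest other split called 510, several times as many, which points to a structure of the samples. Chance is therefore not excluded. The real split gave 0 genes in B-cell-like cells (100 of 100 splits, highest other 555) and CD4-T-cell-like cells (100 of 100 splits, highest other 140). With a mean for each dataset and time, the real split gave the most genes in macrophage-like cells (582 genes, 1 of 98 splits, highest other 343). In CD4-T-cell-like cells the share was under 0.05, but another split gave more genes (54 genes, 3 of 100, highest other 62). These shares were not adjusted for the number of comparisons and do not exclude chance. Nor can chance be excluded in B-cell-like cells (18 genes, 9 of 100, highest other 42). For sex by IFNα with the datasets pooled, the real split gave 0 genes in each class, and as many or more came from 46 of 46 splits in macrophage-like cells (highest other 11), 48 of 48 in B-cell-like cells (322) and 48 of 48 in CD4-T-cell-like cells (37). For differences between classes the 20 of 20 splits are too few for a share under 0.05, with a real value of 0 genes for each pair and highest others of 163 for macrophage against B cell, 136 for macrophage against T cell and 2 for B against T cell.

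Differences between groups within Dataset B were seen between sexes and between classes. The sex by IFNα term called 7 genes in macrophage-like cells, such as Ifit3 (1.86 ± 0.34), where it rests on 1 mouse of each sex at 1 h and at PBS, and 8 in B-cell-like cells, such as Cd69 (1.07 ± 0.24). The response differed between classes for 350 genes between macrophage-like and B-cell-like cells, 126 between macrophage-like and CD4-T-cell-like cells and 156 between B-cell-like and CD4-T-cell-like cells.

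Single mice lay far from the others in 2 of 30 groups tested, where chance flags about 1 in 20 groups. The share of macrophage-like cells above the PBS threshold was 38.3% in the Dataset B female at 1 h and between 0.641% and 5.11% in the other 3 mice of that time. The share of cells left out was 23.5% in the Dataset B female at 3 h and between 30.5% and 34.6% in the other mice of Dataset B. Droplets that no comparison used also carried the interferon signal in Dataset B, where 41.7% of negative droplets and 45.0% of doublets lay above the PBS threshold, against 4.41% of droplets of the PBS mice. Droplets of single mice lay above it in 42.4%, 67.9% and 86.1% of cases at 1, 2 and 3 h, so that the 2 values lie within the range that a mixture of mice spans.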

How the results depend on the processing

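Most named genes held their direction and side of the threshold. Of the values of named genes under the alternatives, 26650 kept both, 1324 kept their direction and no longer passed, 458 passed anew and 1 turned its sign. Of the counts of genes, 1072 stayed within 1.5 times the reported count and 360 moved, of the counts of gene lists 11 and 19, and of the shares of cells above the threshold 463 and 19. The model with a mean for each dataset and time, the reversed times and the shares within each dataset were chosen after seeing the data, and the other alternatives before the data were examined. Values below are counts of genes unless stated, and where the text names no cause, the cause was not tested. Thinning lowers depth and the added log2 change narrows the calls by construction. Counts moved by thinning fell, except sex by IFNα in CD4-T-cell-like cells of Dataset B (0 to 1) and pooled macrophage against B cell (0 to 3).

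DESeq2 gave, within Dataset B, 777 at 3 h, 573 at 3 h against 1 h and 3 for sex by IFNα in macrophage-like cells. B-cell-like cells had 339 at 1 h, 353 at 2 h, 507 at 3 h, 101 at 3 h against 1 h and 2 for sex by IFNα. CD4-T-cell-like cells had 131 at 1 h, 156 at 2 h, 199 at 3 h and 65 at 3 h against 1 h. Class differences numbered 137 for macrophage against B cell, 71 for macrophage against T cell and 88 for B against T cell. DESeq2 also called, in Dataset A as labelled, 159 at 1 h, 986 at 2 h, 1448 at 3 h and 860 at 3 h against 1 h in macrophage-like cells. B-cell-like cells had 31 at 1 h, 154 at 2 h, 553 at 3 h and 537 at 3 h against 1 h. CD4-T-cell-like cells had 2 at 1 h, 105 at 2 h, 324 at 3 h and 306 at 3 h against 1 h. DESeq2 also gave, with the datasets pooled, 1 at 1 h, 2 at 3 h against 1 h and 147 for sex in macrophage-like cells. B-cell-like cells had 29 at 1 h, 1 at 2 h and 21 at 3 h against 1 h. CD4-T-cell-like cells had 0 at 1 h. Class differences numbered 30 for macrophage against B cell. DESeq2 also called, for sex with a mean per dataset and time, 1 in B-cell-like cells, and 22 in CD4-T-cell-like cells.

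An added log2 change of at least 1 gave, within Dataset B, 96 at 1 h, 908 at 3 h and 633 at 3 h against 1 h in macrophage-like cells. B-cell-like cells had 364 at 1 h, 462 at 2 h, 474 at 3 h, 73 at 3 h against 1 h and 5 for sex by IFNα. CD4-T-cell-like cells had 111 at 1 h, 181 at 3 h and 36 at 3 h against 1 h. Class differences numbered 168 for macrophage against B cell, 75 for macrophage against T cell and 77 for B against T cell. The added log2 change called, in Dataset A as labelled, 126 at 1 h, 922 at 2 h, 1405 at 3 h and 873 at 3 h against 1 h in macrophage-like cells. B-cell-like cells had 27 at 1 h, 104 at 2 h, 482 at 3 h and 545 at 3 h against 1 h. CD4-T-cell-like cells had 0 at 1 h, 66 at 2 h, 323 at 3 h and 309 at 3 h against 1 h. The added log2 change gave, with the datasets pooled, 5 for sex in macrophage-like cells, 5 at 1 h and 10 at 3 h against 1 h in B-cell-like cells, and 0 at 1 h in CD4-T-cell-like cells. The added log2 change called, for sex with a mean per dataset and time, 53 in macrophage-like cells, 1 in B-cell-like cells, and 0 in CD4-T-cell-like cells.

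Thinning the class sums to equal depth gave, within Dataset B, 33 at 1 h, 116 at 2 h, 282 at 3 h, 187 at 3 h against 1 h and 2 for sex by IFNα in macrophage-like cells. B-cell-like cells had 358 at 1 h, 392 at 2 h, 612 at 3 h and 179 at 3 h against 1 h. CD4-T-cell-like cells had 1 for sex by IFNα. Class differences numbered 32 for macrophage against B cell, 20 for macrophage against T cell and 68 for B against T cell. The thinned sums called, in Dataset A as labelled, 81 at 1 h, 503 at 2 h, 699 at 3 h and 342 at 3 h against 1 h in macrophage-like cells, and 688 at 3 h in B-cell-like cells. The thinned sums gave, with the datasets pooled, 0 at 1 h in B-cell-like cells, 0 at 1 h in CD4-T-cell-like cells, and 3 for macrophage against B cell. The thinned sums called, for sex with a mean per dataset and time, 217 in macrophage-like cells, and 6 in B-cell-like cells.

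Fitting Dataset B alone gave, within Dataset B, 242 at 1 h in macrophage-like cells, 178 at 3 h against 1 h and 9 for sex by IFNα in CD4-T-cell-like cells, and 237 for B against T cell. Dataset B alone called, in place of the pooled counts, 242 at 1 h, 482 at 2 h, 1784 at 3 h, 1430 at 3 h against 1 h and 235 for sex in macrophage-like cells. B-cell-like cells had 805 at 1 h, 853 at 2 h, 1239 at 3 h, 495 at 3 h against 1 h, 125 for sex and 10 for sex by IFNα. CD4-T-cell-like cells had 254 at 1 h, 298 at 2 h, 360 at 3 h, 178 at 3 h against 1 h, 87 for sex and 9 for sex by IFNα. Class differences numbered 318 for macrophage against B cell, 109 for macrophage against T cell and 158 for B against T cell. Dataset B alone gave, for sex with a mean per dataset and time, 235 in macrophage-like cells, 125 in B-cell-like cells, and 87 in CD4-T-cell-like cells. Fitting Dataset A alone gave, in Dataset A as labelled, 180 at 1 h in B-cell-like cells, and 15 at 1 h in CD4-T-cell-like cells. Dataset A alone called, in place of the pooled counts, 281 at 1 h, 1428 at 2 h, 1951 at 3 h, 1256 at 3 h against 1 h, 525 for sex and 4 for sex by IFNα in macrophage-like cells. B-cell-like cells had 180 at 1 h, 413 at 2 h, 1099 at 3 h, 953 at 3 h against 1 h, 3 for sex and 6 for sex by IFNα. CD4-T-cell-like cells had 15 at 1 h, 225 at 2 h, 611 at 3 h, 554 at 3 h against 1 h and 16 for sex. Class differences numbered 536 for macrophage against B cell, 311 for macrophage against T cell and 5 for B against T cell. Dataset A alone gave, for sex with a mean per dataset and time, 3 in B-cell-like cells, and 16 in CD4-T-cell-like cells.

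Reading the times of Dataset A in reverse, an alternative chosen after seeing the data, gave, with the datasets pooled, 243 at 1 h, 1378 at 2 h, 2790 at 3 h, 2093 at 3 h against 1 h, 625 for sex and 2 for sex by IFNα in macrophage-like cells. B-cell-like cells had 1116 at 1 h, 1447 at 2 h, 1951 at 3 h, 954 at 3 h against 1 h, 23 for sex and 2 for sex by IFNα. CD4-T-cell-like cells had 345 at 1 h, 570 at 2 h, 698 at 3 h, 259 at 3 h against 1 h, 44 for sex and 7 for sex by IFNα. Class differences numbered 364 for macrophage against B cell, 207 for macrophage against T cell and 116 for B against T cell. Fitting only the groups compared gave, in Dataset A as labelled, 41 at 1 h in B-cell-like cells, and 12 at 1 h in CD4-T-cell-like cells. The smaller fit called, with the datasets pooled, 4 at 1 h in macrophage-like cells, 264 at 1 h and 6 at 2 h in B-cell-like cells, and 10 at 1 h in CD4-T-cell-like cells.

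Keeping all genes without an expression filter gave, within Dataset B, 19 for sex by IFNα in macrophage-like cells, and 1 for sex by IFNα in CD4-T-cell-like cells. The unfiltered fit called, in Dataset A as labelled, 10 at 1 h in CD4-T-cell-like cells. The unfiltered fit gave, with the datasets pooled, 48 at 1 h, 14 at 2 h and 2 for sex in B-cell-like cells. CD4-T-cell-like cells had 2 at 1 h, 1 at 2 h, 2 at 3 h, 19 at 3 h against 1 h and 3 for sex. Class differences numbered 122 for macrophage against B cell, 2 for macrophage against T cell and 17 for B against T cell. The unfiltered fit called, for sex with a mean per dataset and time, 60 in B-cell-like cells. A minimum count of 50 gave, within Dataset B, 1 for sex by IFNα in macrophage-like cells. That minimum called, with the datasets pooled, 1 at 1 h and 0 at 3 h against 1 h in B-cell-like cells, 0 at 1 h in CD4-T-cell-like cells, and 1 for macrophage against B cell. Relative log expression size factors gave, within Dataset B, 4 for sex by IFNα in macrophage-like cells. These factors called, with the datasets pooled, 2 at 1 h in B-cell-like cells, and 3 for macrophage against B cell.

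A hashtag margin gave, within Dataset B, 98 for B against T cell. The margin called, with the datasets pooled, 26 at 1 h in B-cell-like cells, and 12 for macrophage against B cell. The margin gave, for sex with a mean per dataset and time, 1050 in macrophage-like cells, and 35 in CD4-T-cell-like cells. With this margin Hbb-bt, a hemoglobin gene, turned from 1.64 to -0.21 for sex by IFNα in B-cell-like cells of Dataset B, and the cause was not tested. A stricter cell filter gave, within Dataset B, 12 for sex by IFNα in macrophage-like cells, and 5 for sex by IFNα in B-cell-like cells. The stricter filter called, with the datasets pooled, 6 at 1 h and 12 at 3 h against 1 h in B-cell-like cells, and 2 for macrophage against B cell. The stricter filter gave, for sex with a mean per dataset and time, 1079 in macrophage-like cells. Removing Scrublet doublets gave, with the datasets pooled, 3 for macrophage against B cell.

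Leaving out the dataset term (no replicate block) gave, with the datasets pooled, 2 for sex in macrophage-like cells, 0 at 1 h and 0 at 3 h against 1 h in B-cell-like cells, and 0 at 1 h in CD4-T-cell-like cells.

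Of the tests of gene lists, camera with an estimated correlation called 0 against 33 in macrophage-like cells pooled, 21 against 35 in macrophage-like cells within Dataset B, 23 against 41 in macrophage-like cells in Dataset A, 0 against 10 in macrophage-like cells for sex, 0 against 29 in B-cell-like cells pooled, 12 against 36 in B-cell-like cells within Dataset B, 7 against 36 in B-cell-like cells in Dataset A, 0 against 6 in B-cell-like cells for sex, 0 against 19 in CD4-T-cell-like cells pooled, 18 against 30 in CD4-T-cell-like cells in Dataset A and 0 against 7 in CD4-T-cell-like cells for sex. The rotation test fry called 1 against 33 in macrophage-like cells pooled, 4 against 29 in B-cell-like cells pooled, 0 against 6 in B-cell-like cells for sex, 0 against 19 in CD4-T-cell-like cells pooled and 0 against 7 in CD4-T-cell-like cells for sex. Camera on Dataset B alone called 50 against 33 in macrophage-like cells pooled and 36 against 19 in CD4-T-cell-like cells pooled. Camera on Dataset A alone called 42 against 19 in CD4-T-cell-like cells pooled.

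With 500 UMIs per cell the share above the PBS threshold differed from PBS, within Dataset B, by 36.9 points at 2 h and 92.9 points at 3 h in macrophage-like cells, 79.1 points at 2 h and 79.4 points at 3 h in B-cell-like cells, 47.8 points at 2 h in CD4-T-cell-like cells. With the 99th percentile as threshold the share above it differed from PBS, within Dataset B, by 39 points at 2 h and 97.8 points at 3 h in macrophage-like cells, 71.4 points at 2 h and 70.9 points at 3 h in B-cell-like cells, 37.6 points at 2 h and 62.1 points at 3 h in CD4-T-cell-like cells. With the 99th percentile as threshold the share above it differed from PBS, in Dataset A as labelled, by -0.386 points at 2 h and -0.791 points at 3 h in B-cell-like cells, -0.715 points at 2 h and -0.715 points at 3 h in CD4-T-cell-like cells. With the hashtag margin the share above the PBS threshold differed from PBS, within Dataset B, by 89.6 points at 3 h in B-cell-like cells, 51.6 points at 2 h in CD4-T-cell-like cells.

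Leaving out each mouse in turn, in fits where a lone mouse is assumed to vary like the other groups, gave ranges within Dataset B of macrophage-like counts of 55 to 168 at 1 h (lowest without the PBS female of Dataset B), 665 to 1674 at 3 h (lowest without the PBS female of Dataset B), 536 to 1192 at 3 h against 1 h (lowest without the 1 h female of Dataset B) and 4 to 46 for sex by IFNα (lowest without the PBS male of Dataset A). B-cell-like counts within Dataset B ranged over 350 to 754 at 1 h (lowest without the 1 h female of Dataset B), 575 to 1194 at 3 h (lowest without the PBS female of Dataset B), 77 to 414 at 3 h against 1 h (lowest without the 3 h female of Dataset B) and 7 to 20 for sex by IFNα (lowest without the 3 h female of Dataset A). CD4-T-cell-like counts within Dataset B ranged over 112 to 234 at 1 h (lowest without the PBS female of Dataset B), 64 to 170 at 3 h against 1 h (lowest without the 1 h male of Dataset B) and 0 to 2 for sex by IFNα (lowest without the PBS male of Dataset A). Differences between classes within Dataset B ranged over 107 to 410 for macrophage against B cell (lowest without the PBS female of Dataset B), 40 to 146 for macrophage against T cell (lowest without the PBS female of Dataset B) and 50 to 180 for B against T cell (lowest without the PBS female of Dataset B).

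In Dataset A as labelled the macrophage-like ranges were 17 to 388 at 1 h (lowest without the PBS female of Dataset A), 320 to 1827 at 2 h (lowest without the PBS female of Dataset A), 531 to 2674 at 3 h (lowest without the PBS female of Dataset A) and 493 to 1474 at 3 h against 1 h (lowest without the 1 h female of Dataset A). B-cell-like ranges of Dataset A were 18 to 183 at 1 h (lowest without the PBS female of Dataset A), 68 to 395 at 2 h (lowest without the 2 h female of Dataset A), 500 to 1096 at 3 h (lowest without the 3 h female of Dataset A) and 568 to 1014 at 3 h against 1 h (lowest without the 3 h female of Dataset A). CD4-T-cell-like ranges of Dataset A were 4 to 16 at 1 h (lowest without the 1 h male of Dataset A), 90 to 229 at 2 h (lowest without the 2 h male of Dataset A) and 373 to 614 at 3 h (lowest without the PBS female of Dataset A).

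With the datasets pooled, macrophage-like counts ranged over 0 to 1 at 1 h, 0 to 6 at 3 h, 0 to 30 at 3 h against 1 h, 7 to 36 for sex and 0 to 1 for sex by IFNα. Pooled B-cell-like counts ranged over 0 to 57 at 1 h, 0 to 2 at 2 h, 0 to 43 at 3 h against 1 h and 0 to 1 for sex by IFNα. Pooled CD4-T-cell-like counts ranged over 0 to 3 at 1 h, 0 to 2 at 3 h and 0 to 8 at 3 h against 1 h. Pooled differences between classes ranged over 0 to 27 for macrophage against B cell and 0 to 1 for B against T cell. Macrophage-like sex counts with a mean per dataset and time ranged over 368 to 623 for sex (lowest without the 1 h male of Dataset A). B-cell-like sex counts of that model ranged over 3 to 35 for sex (lowest without the 3 h male of Dataset B). CD4-T-cell-like sex counts of that model ranged over 32 to 108 for sex (lowest without the 1 h female of Dataset B).

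Differences in share from PBS within Dataset B ranged most at 1 h, over 1.57 to 34.8 points in macrophage-like, 50.3 to 81.5 in B-cell-like and 14.2 to 44.4 in CD4-T-cell-like cells (lowest without the 1 h female, highest without the 1 h male). At 2 h they ranged over 57.5 to 64.2 in macrophage-like and 50.9 to 54.2 in CD4-T-cell-like cells. With the datasets pooled the B-cell-like difference at 1 h ranged over 18.3 to 45.6.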

Other observations

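Core ISG levels were also higher after IFNα in Dataset B in clusters outside the 3 classes, among them those with markers of natural killer cells and monocytes. In the cluster with monocyte markers, core ISG UMIs per 1000 were 11.7 in the PBS female and 12.7 in the PBS male, 39.4 and 30.6 at 1 h, 36.4 in the male at 2 h and 47.7 and 42.0 at 3 h, the highest baseline of the clusters listed here. The natural killer cluster held 5.68 and 6.14 in the PBS mice, 17.5 and 13.2 at 1 h and 25.4 and 17.8 at 3 h.

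Core ISG levels were also higher at 3 h than in PBS mice in clusters with markers of regulatory, γδ and CD8 T cells. Core ISG UMIs per 1000 in the regulatory T cell cluster were 7.42 in the PBS female and 7.63 in the PBS male and 31.6 and 24.6 at 3 h. They were 7.02 and 7.31 against 33.5 and 25.4 in the γδ T cell cluster, and 6.33 and 5.99 against 21.2 and 19.2 in the CD8 T cell cluster. These clusters were named from their marker genes and not tested between groups.

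Some genes were called higher in all 3 classes within Dataset B, whose cells come from the same mice. Among 8537 genes tested in each class, 75 were higher in all 3 at 1 h, 151 at 2 h and 205 at 3 h. Of the genes lower than PBS, 0, 0 and 1 were lower in all 3.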
